A study of Homo sapiens with 6 samples.

How the data were processed

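RNA was taken from cells labelled MCF-7 after transfection with a plasmid for His-tagged Trichinella spiralis tropomyosin or a control plasmid. Per the labels' protocols, libraries were made with a KAPA stranded kit. Groups and replicate numbers 1 to 3 come from the sample titles. Per the submitters' processing notes, StringTie and the build GRCh37 were used, with no version given. The aligner and annotation release are not given in the sources used here, nor is whether strand was used in the assignment of fragments. The authors deposited FPKM values per library for annotated genes, annotated transcripts, unannotated genes and unannotated transcripts. Gene values are not the sums of the listed transcripts. The authors' deposited tables of comparisons hold log2 changes, folds (ratio), p-values and q-values, and 2 columns headed FPKM that hold group means of log2(FPKM + 1). The deposited log2 change equals the difference of those means within rounding. The test behind the authors' p-values is not given. Of the unannotated genes, 6394 of 13385 (47.8%) overlap a listed gene on the same strand, so these loci can include annotated transcripts.

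FPKM are not counts, so no test for counts was run. Depth was estimated from the spacing of low FPKM × length values at 4662 single-exon unannotated loci, where values below 60 fell on whole multiples of a step. Between 93.7% and 96.6% of values per library were whole within 0.1 of a step, where chance gives 20%. If 1 step is 1 covered base, covered megabases were 3786, 4014 and 4872 in the control libraries and 3772, 3474 and 3712 in the tropomyosin libraries. These are bases, not fragments, so no counting interval was formed.

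Values were tested as log2(FPKM + 1) for features with a mean of at least 1 over the 6 libraries, with limma 3.58.1 in R 4.3.3 (trend and robust, two-sided) and Benjamini-Hochberg adjustment over the features tested, at an adjusted p under 0.05. Gene lists, 36 in all, were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the 33 lists with at least 4 tested members. fry, which asks whether a list's genes move one way on balance, passed 0 lists after adjustment. In 9 lists that did not pass, the median, the mean and the test direction differed in sign: G1 cyclins and CDK inhibitors, interferons and cytosolic sensing, mitosis and G2/M, PI3K, AKT and mTOR components, nuclear-encoded oxidative phosphorylation, NRF2 and ferroptosis, cytosolic ribosomal proteins, epithelial-mesenchymal transition and invasion, and antigen presentation. Lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 10 largest rises and 10 largest falls past the threshold, filled up by the smallest unadjusted p among genes whose groups did not overlap, the human tropomyosins, up to 4 members per list with the smallest p, and the 5 largest folds in each of the authors' tables. Not every gene so chosen is named in the text. Named transcripts were all those past the threshold. Overlapping genes, other transcripts of the same genes, MSTRG.28984.4 and further marker genes were named after their values were seen.

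The tests were tried on simulated data with 200 features changed by 1.5-, 2- or 4-fold on the log2(FPKM + 1) scale and the real spread of each feature. The changed features were drawn from those with a mean log2(FPKM + 1) of at least 2.5, so recovery among lower ones was not measured. This gave 4 false calls among genes, 1 among transcripts and 7 among unannotated genes. Noise was drawn independently for each feature and library, so variation shared by many features was not simulated. Of unchanged simulated genes, 4.89% had an unadjusted p under 0.05, against 2.48% of the real genes. False calls and recovery under such shared variation were not measured. In a simulated list test with genes drawn independently of each other, a list of 15 genes shifted by 0.3 was recovered with 0 false calls. Correlated members were not simulated, so false calls in lists such as the mitochondrial mRNAs (estimated correlation 0.464) were not measured. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5, each library left out, the replicate number as a block, median-ratio scaling, quantile normalization, limma without trend and robust, array weights, a fold of at least 1.5, and, added later, a correction for GC content. GC content came from GENCODE release 29 transcripts matched by gene identifier for 99.2% of tested genes, and no coordinates of that build were used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.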

Results

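Cells labelled as human MCF-7, an established breast cancer line, were transfected. They received either a plasmid that carried tropomyosin of the parasitic roundworm Trichinella spiralis or a control plasmid. Tropomyosin is an actin-binding protein of muscle and cytoskeleton. RNA of each group was sequenced in 3 libraries, 6 in all, and the comparison asked which transcripts differ between cells given the parasite gene and cells given the control plasmid. Expression of the parasite gene was not measured here. A small effect of it and little expression of it can therefore not be told apart. The deposited gene table listed 11699 annotated genes in FPKM, a count of fragments scaled to transcript length and library depth, of which 10805 had a mean of at least 1 and were tested. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries. Depth was read from the smallest steps between low values, and the deepest library held 1.40 times as much as the shallowest. The libraries were alike at the gene level, with correlations across genes of 0.963 to 0.981 on the log2 scale.

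Few annotated genes differed. MIS12, which encodes a kinetochore protein, rose from 3.96 ± 0.38 FPKM (SD, n = 3) to 18.2 ± 0.42 (SD, n = 3). RBMS2, which encodes an RNA-binding protein, rose from 1.70 ± 0.23 to 9.67 ± 0.68 FPKM. HES2, a transcription factor of the hairy and enhancer of split family, fell from 3.79 ± 0.23 to 0.696 ± 0.144 FPKM. On the log2(FPKM + 1) scale, which understates changes of low genes, the changes were 1.96 (SE 0.094, adjusted p = 0.00141) for MIS12, 1.98 (SE 0.105, adjusted p = 0.00141) for RBMS2 and -1.50 (SE 0.102, adjusted p = 0.00539) for HES2 in limma with Benjamini-Hochberg adjustment. All 3 libraries of one group lay outside the range of the other for each of these genes. MIS12 lies on chromosome 17 at 5389605 to 5394134 of GRCh37 on the plus strand and overlaps DERL2 on the other strand, which stood at 5.86 ± 1.42 and 5.94 ± 0.55 FPKM. RBMS2 lies on chromosome 12 at 56915713 to 56989980 on the plus strand and overlaps BAZ2A on the other strand, at 12.7 ± 1.3 and 13.8 ± 0.1 FPKM. Whether strand was used in counting is not given in the sources used here, so values of overlapping genes are uncertain. HES2 lies on chromosome 1 at 6472478 to 6484730 on the minus strand. A locus assembled within the bounds of each gene was deposited separately, covering 91.9% of the length of MIS12, all but 29 and 3 bases at the ends of RBMS2, and 77.0% of HES2, without the 2814 bases at the 3' end of HES2. Its value was 3.66 ± 1.32 FPKM in the control and 12.2 ± 0.85 in the tropomyosin libraries for MIS12, and 2.52 ± 0.90 and 7.94 ± 3.02 FPKM for RBMS2. At HES2 it was 2.32 ± 0.21 FPKM in the control libraries and 3.38 ± 0.20 in the tropomyosin libraries, against the direction of the gene. None of these 3 locus values passed adjustment over the unannotated genes, with adjusted p of 0.511, 1.000 and 1.000. HES2 no longer passed without control replicate 1 (adjusted p = 0.0506 in limma, against 0.0174 to 0.0451 without any other library), and with the filter raised to a mean of at least 5 it was not tested, since its mean lies below that. With the replicate number as a block it did not pass either (adjusted p = 0.0813 in limma).

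**Figure D1:**
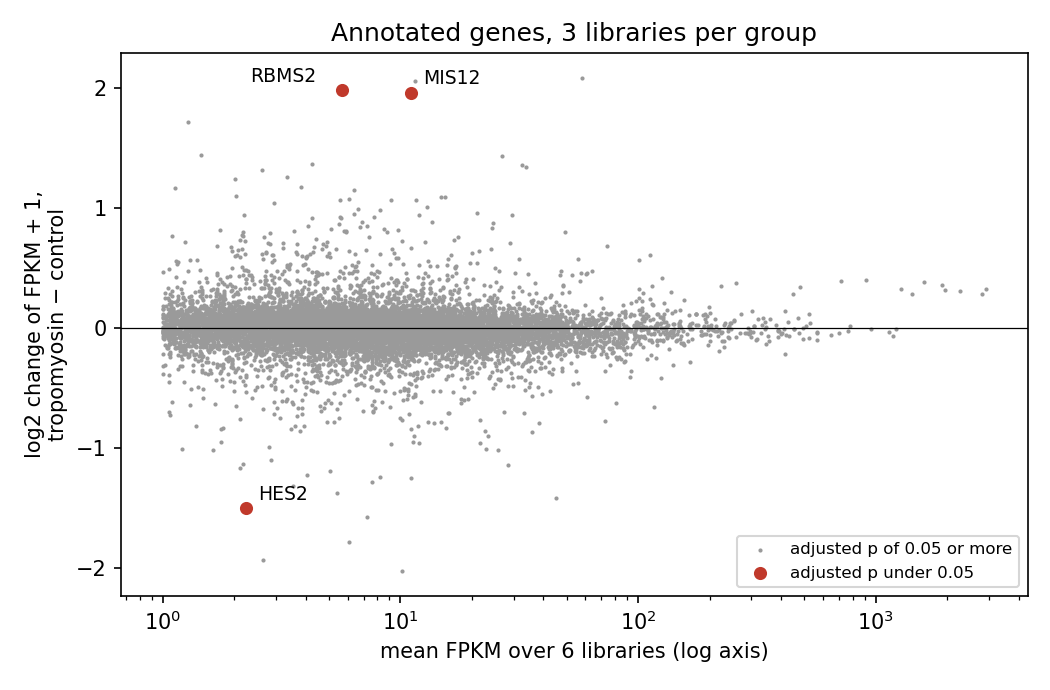
Log2 change of FPKM + 1 (tropomyosin minus control plasmid) against mean FPKM over 6 libraries (log axis), 1 point per tested gene. MIS12, RBMS2 and HES2, in red, are the genes past the threshold, at 1.96, 1.98 and -1.50.

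At an unadjusted p under 0.05 there were 268 genes, or 2.48% of those tested. In 724 genes (6.7%) the groups did not overlap, where chance gives 10% for 3 against 3. For 10084 genes (93.3%) the 95% interval of the change of FPKM + 1 lay within 2-fold either way. For 8892 (82.3%) it lay within 1.5-fold. For genes of low FPKM these limits allow larger changes of FPKM itself. With 200 of the better expressed of the 10805 genes changed in simulated data, the test recovered 97.0% of 4-fold, 71.6% of 2-fold and 31.3% of 1.5-fold changes. The number of genes called was 2, 6 and 5 without control replicates 1, 2 and 3, and 7, 9 and 8 without tropomyosin replicates 1, 2 and 3. Of the 10 ways to divide the 6 libraries into 3 and 3, 9, the real one included, gave at least 3 called genes, up to 13.

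The genes nearest to the threshold did not pass it. Among higher values were CLTA, the clathrin light chain A, with 35.6 ± 3.7 FPKM in the control and 62.7 ± 2.2 in the tropomyosin libraries (adjusted p = 0.161, limma), and AK6, an adenylate kinase, with 13.9 ± 0.8 and 20.3 ± 1.3 FPKM (adjusted p = 0.557). ANKLE1, HNRNPA1L2, KCTD6, EMSY and ZNF346 had log2 changes of 0.61, 1.26, 0.76, 0.66 and 0.67. AL136295.1 was listed at 0 in each control library and at 2.55 ± 1.80 FPKM in the tropomyosin libraries. Among lower values, TGIF2, a homeobox corepressor of TGF-beta signalling, had 11.3 ± 0.5 and 3.21 ± 0.99 FPKM (adjusted p = 0.0804), and it overlaps the readthrough gene TGIF2-C20orf24. SLC25A24, a mitochondrial carrier, had 5.45 ± 0.86 and 1.61 ± 0.40 FPKM (adjusted p = 0.106). PRKACA, a catalytic subunit of protein kinase A, and ADCY6, an adenylate cyclase, had log2 changes of -0.77 and -0.81 (adjusted p = 0.219 and 0.411). VPS35, a retromer subunit, RNPEPL1, CDK3, the inhibitor of NF-kB NFKBIE, and CIAPIN1 had log2 changes of -0.90, -0.67, -0.72, -1.10 and -0.50. CDK3 overlaps the readthrough gene TEN1-CDK3, whose own values were 1.94 ± 0.44 and 3.50 ± 0.31 FPKM. CLTA, AK6, AL136295.1, RNPEPL1 and CIAPIN1 also overlap other listed genes. Assembled loci that overlap these genes, with bounds that differ from theirs, had log2 changes of -0.77 for PRKACA and -1.25 for SLC25A24 (over 8.03% of that gene), but 0.09 for ADCY6, -0.07 for CDK3, -0.04 for ANKLE1, -0.07 for AL136295.1 and 0.16 for HNRNPA1L2. Those for EMSY and ZNF346 were 0.31 and 0.15.

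The 13 mRNAs encoded by the mitochondrial genome, which give subunits of the respiratory chain and ATP synthase, were all higher with the tropomyosin plasmid. As a list they rose by a median of 0.32 on the log2 scale (1.25-fold), with single changes from 0.28 to 0.40 (camera with a preset correlation, adjusted p = 3.16e-15). With an estimated correlation of 0.464 between the members, the adjusted p = 0.545, so the call rests on the preset value. MT-CO3 stood at 1662 ± 100 and 2130 ± 170 FPKM, MT-CYB at 621 ± 77 and 812 ± 44, and MT-ND5 at 789 ± 143 and 1032 ± 43 FPKM. None of the 13 passed over all genes tested, while 9 passed adjusted over the list alone. Together they held 8.09 ± 0.67% (SD, n = 3) of the summed gene FPKM in the control libraries and 10.0 ± 0.6% in the tropomyosin libraries, with no overlap (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 can give). Quantile normalization, which gives every library the same set of values, lowered the median to 0.16 with an adjusted p of 0.00117, within a range of 1.08e-15 to 0.545 over all alternatives. The 32 tested genes of nuclear-encoded oxidative phosphorylation had a median of -0.01.

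**Figure D2:**
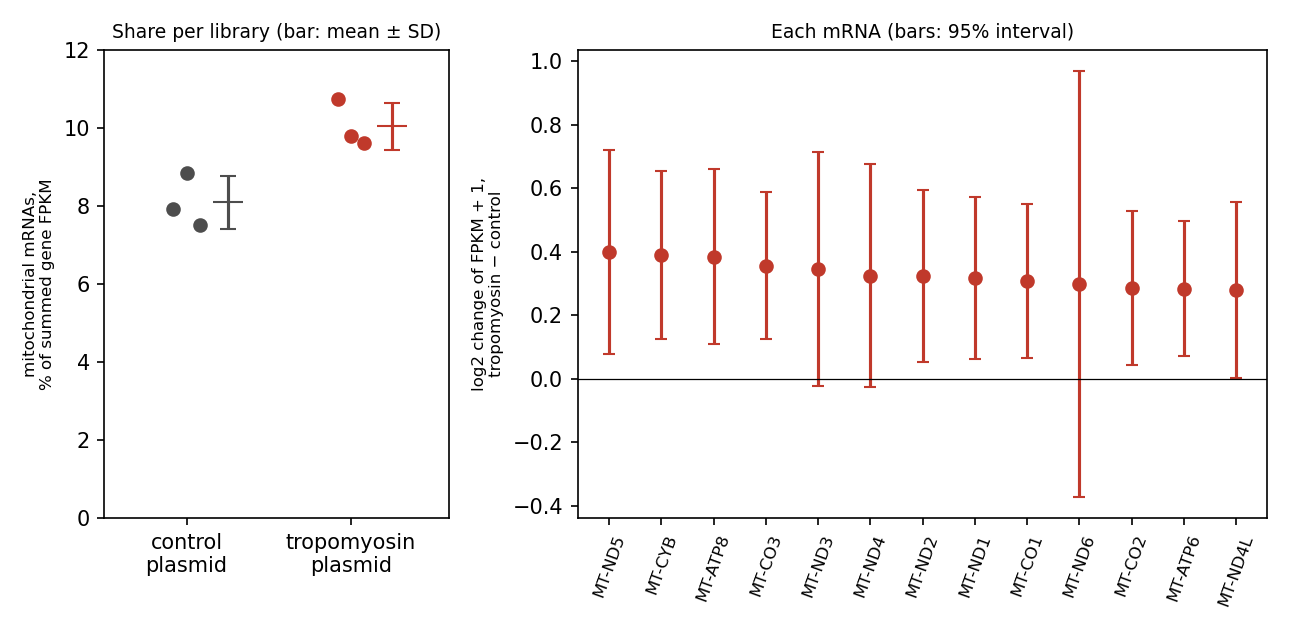
Left, share of the summed gene FPKM held by the mitochondrial mRNAs in each library, with mean and SD, 8.09% for the control and 10.0% for the tropomyosin plasmid. Right, log2 change of FPKM + 1 of each of the 13 mRNAs with its 95% interval; all points lie between 0.28 and 0.40, and the intervals of MT-ND3, MT-ND4 and MT-ND6 include 0.

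DNA replication and G1/S genes fell slightly as a list (median -0.08, 24 of 30 negative, camera adjusted p = 0.0273), and with an estimated correlation the adjusted p was 0.963. MCM2, a subunit of the replicative helicase, had 38.7 ± 1.2 and 30.4 ± 5.5 FPKM, and MCM3 59.8 ± 5.2 and 50.8 ± 5.2, and neither passed the gene test. Heat shock genes and chaperones fell likewise (median -0.07, 14 of 15 negative, adjusted p = 0.0305), with HSP90AA1, a cytosolic chaperone, at 141 ± 5 and 108 ± 25 FPKM. With an estimated correlation the adjusted p of the heat shock list was 0.545. No member of either list passed over all genes or adjusted over the list alone. Quantile normalization ended both calls (adjusted p = 0.179 for each), and median-ratio scaling that of the heat shock list (0.0506). The replication list also did not pass without control replicates 2 and 3 or tropomyosin replicate 1 (adjusted p = 0.164, 0.273 and 0.663), nor the heat shock list without control replicates 1 and 2 or tropomyosin replicates 2 and 3 (0.196, 0.214, 0.290 and 0.0782).

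The other 30 lists with at least 4 tested members did not pass, and none of their members passed over all genes or adjusted over the list alone. The human tropomyosins TPM1, TPM2, TPM3 and TPM4 had log2 changes of -0.07, -0.15, -0.12 and 0.01 (list median -0.10), with TPM4 at 79.2 ± 2.9 and 79.9 ± 0.3 FPKM. The 35 genes of the actin cytoskeleton and tropomyosin partners had a median of -0.04, and VCL, the focal adhesion protein vinculin, stood at 47.8 ± 5.9 and 29.1 ± 13.7 FPKM. SRF and MRTF targets had a median of -0.06. Among growth and death programmes, the medians were 0.08 for p53 targets, -0.03 for apoptosis regulators, 0.00 for G1 cyclins and CDK inhibitors, 0.01 for mitosis and G2/M, and 0.00 for replication-dependent histones. CDK2, a kinase of S-phase entry, had 34.6 ± 0.5 and 28.1 ± 1.1 FPKM, and BCL2L2 had 14.8 ± 0.3 and 5.49 ± 7.69. Signalling lists had medians of 0.05 for immediate early genes, 0.00 for MAPK components and feedback, 0.02 for PI3K, AKT and mTOR components, -0.03 for Wnt targets, -0.03 for TGF-beta and SMAD targets and -0.05 for NF-kB and inflammatory cytokines. The NF-kB median covers 15 of 27 members and the Wnt median 8 of 15. TNF, CXCL1, CXCL10 and PTGS2 of the NF-kB list had no listed value. EGR1, an immediate early transcription factor, had 93.9 ± 6.3 and 115 ± 8 FPKM.

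Innate and antigen lists were near 0 as well, with medians of -0.03 for interferon-stimulated genes, -0.01 for interferons and cytosolic DNA and RNA sensing and -0.03 for antigen presentation. These medians cover 29 of 42, 9 of 18 and 12 of 18 members. IFNB1, IFNL1, IFNL2 and IFNL3 had no listed value, so these interferons were not tested. MX1, MX2, OAS2 and RSAD2 among the interferon-stimulated genes had none either. B2M, the light chain of class I molecules, had 44.9 ± 9.0 and 60.7 ± 2.4 FPKM, and HLA-C 38.2 ± 2.9 and 31.4 ± 1.9. Stress and metabolic lists had medians of 0.00 for the unfolded protein response and endoplasmic reticulum stress, -0.01 for NRF2 and ferroptosis, -0.00 for hypoxia and glycolysis, 0.04 for cholesterol and fatty acid synthesis, -0.03 for autophagy and lysosome and -0.00 for cytosolic ribosomal proteins. The ribosomal list passed in opposite directions when single libraries were left out, with medians of -0.0820 and -0.0751 without control replicate 2 and tropomyosin replicate 1, and 0.0917 and 0.0743 without control replicate 1 and tropomyosin replicate 3. GABARAPL1, an autophagy protein, had 21.5 ± 17.6 and 46.2 ± 3.5 FPKM. Identity lists had medians of -0.10 for luminal epithelial identity, -0.01 for the oestrogen response, -0.07 for basal and myoepithelial markers, -0.01 for epithelial-mesenchymal transition and invasion, -0.02 for fibroblast markers and 0.02 for housekeeping reference genes. Tested were 8 of 20 luminal, 19 of 34 oestrogen response, 4 of 12 basal and 5 of 14 fibroblast genes. CTSD, a lysosomal protease and oestrogen target, had 105 ± 15 and 78.9 ± 3.9 FPKM, and KRT8, a luminal keratin, 96.0 ± 5.1 and 78.9 ± 3.4. Fewer than 4 members were tested for endothelial markers (CDH5, -0.03), immune and haematopoietic markers (CD68, 0.11) and HeLa and HEK293 lineage markers (median of 3 genes, 0.04).

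**Figure D3:**
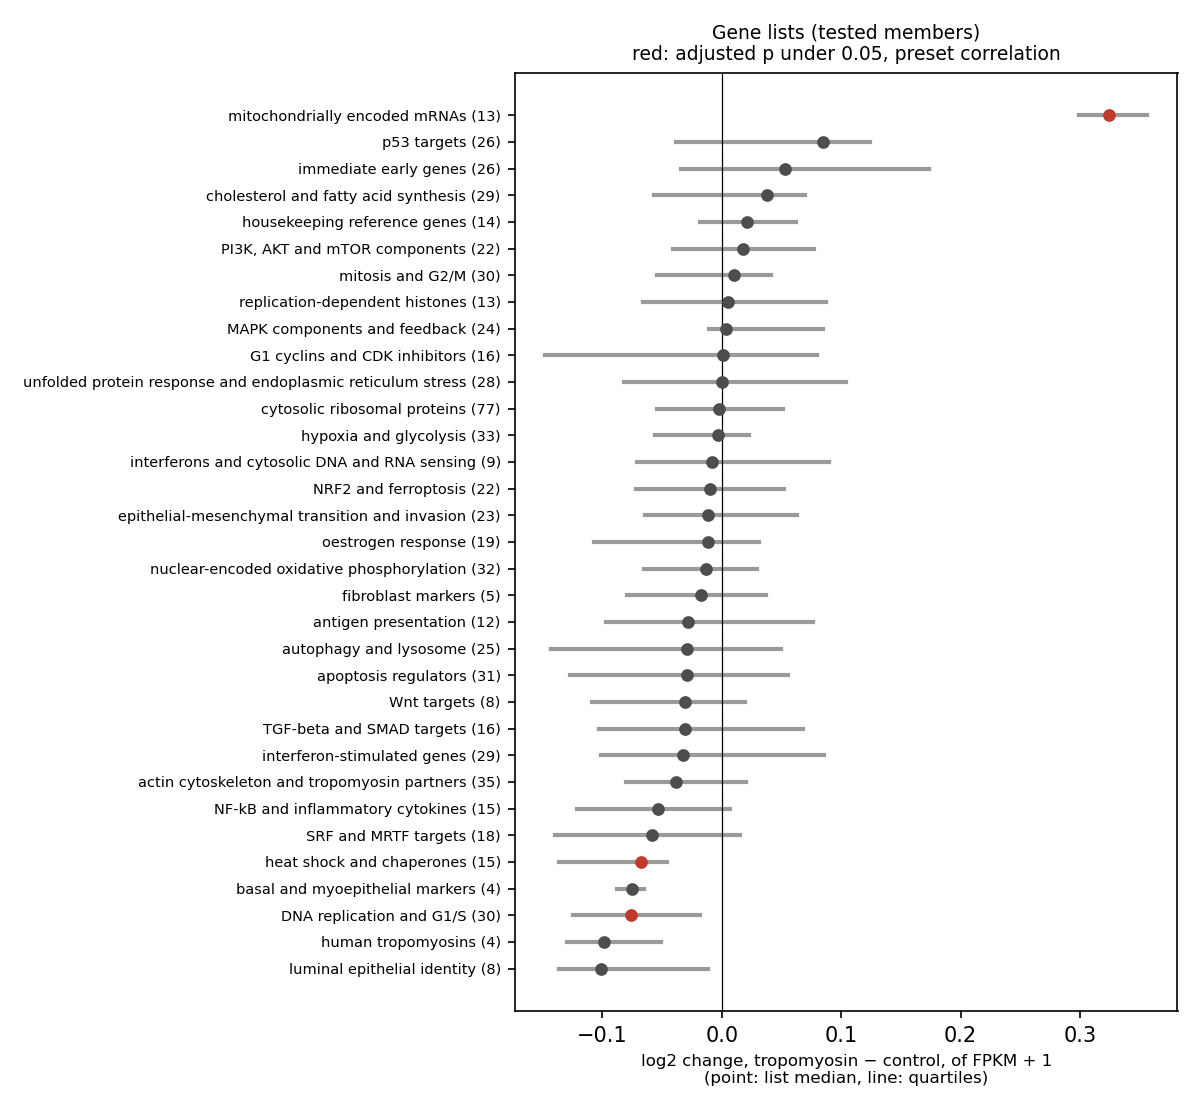
Median log2 change of FPKM + 1 (points) and quartiles (lines) of the tested members of each of 33 lists. The mitochondrial mRNAs stand apart at 0.32, and the lists that did not pass lie between -0.10 and 0.08.

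At the transcript level, 21156 of 29581 annotated transcripts were tested and 6 passed, 3 higher and 3 lower. With the replicate number as a block, 0 passed in limma, with 702 at an unadjusted p under 0.05. Of the 10 ways to divide the 6 libraries into 3 and 3, 8, the real one included, gave at least 6 calls, up to 38. FYN-201, from a gene for a Src family kinase, was listed at 0 or 0.08 FPKM in the control libraries and at 23.2 ± 0.4 FPKM (SD, n = 3) in the tropomyosin libraries (adjusted p = 0.00387, limma). CDK16-202 rose from 4.70 ± 1.21 to 36.3 ± 2.9 FPKM (adjusted p = 0.0486) and COPS8-202, from a gene of the COP9 signalosome, from 0.557 ± 0.565 to 23.7 ± 3.1 (adjusted p = 0.0487). VOPP1-208 fell from 32.7 ± 2.5 to 0.152 ± 0.263 FPKM (adjusted p = 0.00788), and PACSIN3-211 from 30.7 ± 10.6 to 0.0495 ± 0.0302 (adjusted p = 0.0345). RBM28-202 fell from 7.60 ± 0.93 FPKM and was listed at 0 in each tropomyosin library (adjusted p = 0.0280). The 6 transcripts lie in GRCh37 on chromosome 6 at 111982485 to 112080334 (FYN-201), X at 47078087 to 47089396 (CDK16-202), 2 at 237994525 to 238007261 (COPS8-202), 7 at 55538307 to 55605387 (VOPP1-208), 11 at 47199091 to 47207432 (PACSIN3-211) and 7 at 127950533 to 127983924 (RBM28-202).

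The genes of these transcripts did not pass the gene test. The gene FYN was listed at 9.11 ± 0.74 and 9.01 ± 0.37 FPKM, with a log2 change of -0.01 (95% interval -0.23 to 0.21). CDK16 was listed at 24.3 ± 1.0 and 24.2 ± 0.7 FPKM. The interval was wider for COPS8, whose log2 change was 0.53 with a 95% interval from -0.26 to 1.32. Gene values are not totals over transcripts, since FYN-201 alone stood at 23.2 FPKM in the tropomyosin libraries. Flat gene values therefore do not show that the transcripts together stayed level. Other transcripts of the same genes went either way. Against the called one, RBM28-201 stood at 2.76 ± 0.23 and 4.28 ± 0.13 FPKM, PACSIN3-201 at 5.21 ± 8.24 and 40.4 ± 8.6, VOPP1-201 at 0.601 ± 0.228 and 24.9 ± 21.0, and COPS8-201 at 8.31 ± 4.75 and 2.04 ± 0.55. FYN-202 and FYN-205 stood at 6.51 ± 4.66 and 5.69 ± 3.57 FPKM in the control and 1.63 ± 0.61 and 0.624 ± 0.298 in the tropomyosin libraries, and FYN-229 at 2.06 to 10.2 and 2.12 to 2.95 FPKM. CDK16-211 was listed at 53.5, 0 and 38.8 FPKM in the control libraries and at 0 in each tropomyosin library, and VOPP1-207 at 0 in all libraries but tropomyosin replicate 2 (30.7). In its direction, VOPP1-204 stood at 7.74 ± 2.75 FPKM and PACSIN3-204 at 12.6 ± 19.5 in the control libraries, and both were listed at 0 in each tropomyosin library. COPS8-203 stood at 0.188 ± 0.245 and 0.697 ± 0.841 FPKM. With 200 of the better expressed of the 21156 transcripts changed in simulated data, the test recovered 56.1% of 4-fold, 14.9% of 2-fold and 0% of 1.5-fold changes. At an unadjusted p under 0.05 there were 732 transcripts (3.46%). With a pseudocount of 0.1, 2 transcripts passed, FYN-201 and PACSIN3-211. With a mean of at least 5, 1 passed, VOPP1-208, and RBM28-202 was not tested. With no filter 4 passed, as CDK16-202 and COPS8-202 stood at an adjusted p of 0.0504 each. Without control replicates 1, 2 and 3, 15, 19 and 20 transcripts passed, and without tropomyosin replicates 1, 2 and 3, 28, 7 and 0 in limma, the last with 708 at an unadjusted p under 0.05. Of the 6 named transcripts, these fits kept 3, 3, 5, 3, 2 and 0. Among these fits, FYN-201 and VOPP1-208 were lost only without tropomyosin replicate 3 (adjusted p = 0.0613 for each), whereas COPS8-202 passed only without control replicate 3 (0.0158) and CDK16-202 only without control replicate 2 or 3 (0.0316 and 0.0282). RBM28-202 passed without control replicate 1 or tropomyosin replicate 1 (0.0477 and 0.0482), and PACSIN3-211 without control replicate 3 (0.0101). Of 8725 unannotated genes tested, 0 passed in limma, and 196 (2.25%) had an unadjusted p under 0.05. The self-test at that level recovered 93.9% of 4-fold changes.

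**Figure D4:**
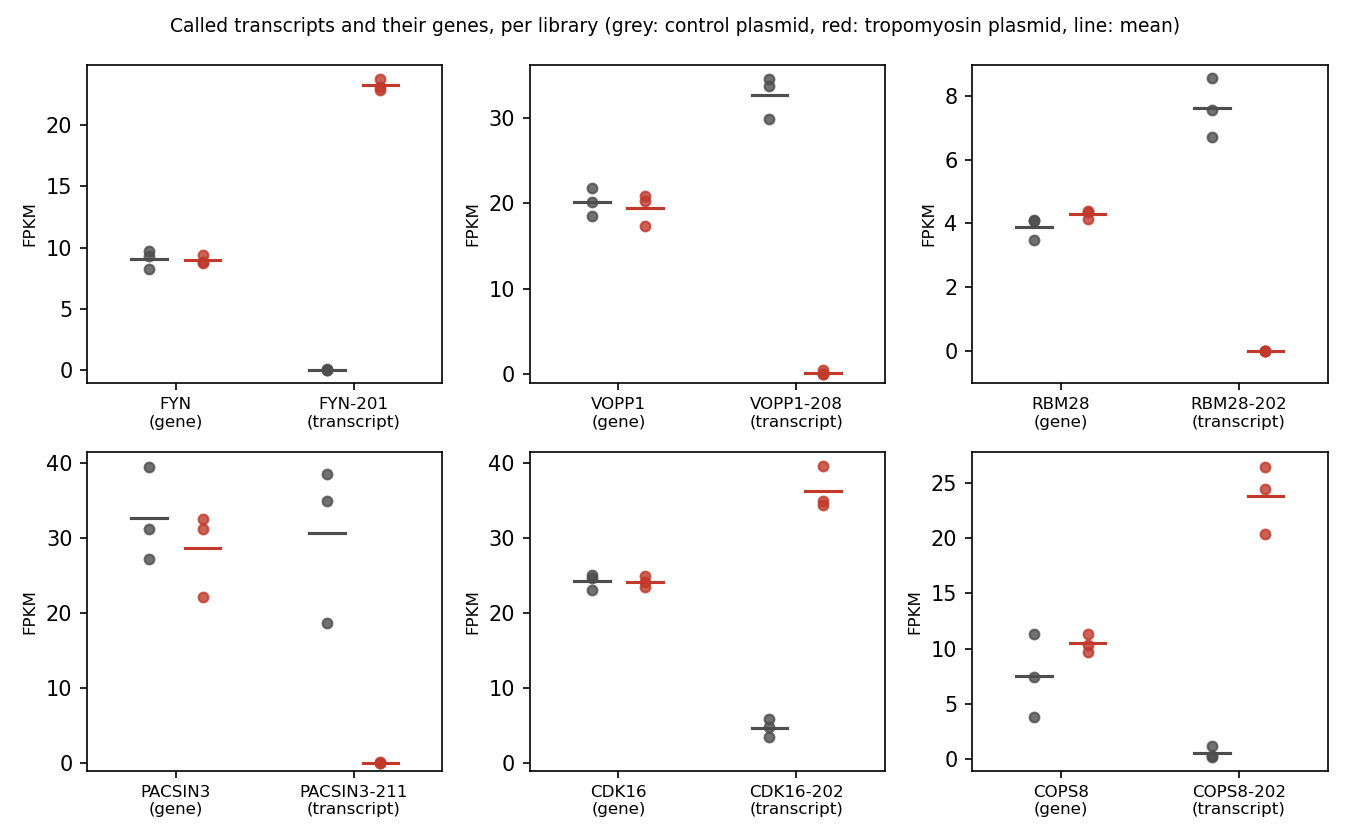
FPKM per library (points; line, mean) of each called transcript and of its gene, grey for the control and red for the tropomyosin plasmid. FYN-201 goes from near 0 to 23.2 FPKM while the listed value of the gene FYN, not a sum of its transcripts, stays near 9.

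The authors' deposited table of changed genes listed 21 higher and 15 lower. Each had an unadjusted p under 0.05 and a fold of at least 1.5 in the authors' deposited table, and these limits applied to its full version returned the same number, 36. No gene reached a q under 0.05 in the authors' deposited table, where 332 had an unadjusted p under 0.05 and the smallest q was 0.0644. The 3 genes called here were among the 36 of the authors' deposited table. The highest fold in the authors' deposited table, which is a fold of FPKM + 1, was that of ARL8B (4.16-fold, q = 1.000). Its values per group were 3.29 ± 0.80 and 19.7 ± 12.5 FPKM. TEN1 was listed there among the lower genes (0.456-fold). For transcripts, the authors' deposited table listed 262 higher and 297 lower, of which 5 had a q under 0.05. Of these 5, only FYN-201 and RBM28-202 were also called here. All 6 transcripts called here were among the 559 of the authors' deposited table, which rests on the same values and an unadjusted p. Of the 533 transcripts in the authors' deposited table whose gene was tested, 494 (92.7%) belonged to genes that differed by less than 1.5-fold in FPKM + 1. Of all tested genes, 82.3% had even their whole 95% interval within 1.5-fold, so at least that share differed by less than 1.5-fold. The exact share was not computed. Whether 92.7% lies above or below it is not known, so the 92.7% alone does not set these transcripts apart.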

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

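The tests of single libraries, of transcripts against genes, of loci and of the splits for genes and transcripts were chosen after the results were seen, and the GC correction after the data were seen but before its own result. Unannotated transcripts lie outside the comparisons of the report and carried calls: 6 were higher and 8 lower of 11110 tested. The highest other split of the 6 libraries gave 26, the real one 14, and 5 of 10 splits gave as many, too few splits for a share under 0.05. The calls included MSTRG.28984.4 at the FYN locus, with 15.8 ± 1.1 and 2.75 ± 0.42 FPKM, opposite to FYN-201. With a pseudocount of 0.1, 0 passed in limma, with 312 at an unadjusted p under 0.05.

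The first pattern is the rise of the 13 mitochondrial mRNAs. Over tested genes the log2 change had a Spearman correlation of -0.29 with GC content, so a trend with GC content was present. This trend as the whole cause is argued against. After its removal the median was 0.30, against 0.32 before, and tested nuclear genes of the same GC range had a median of 0.03. A single library as the cause is argued against too, since the lowest median without any 1 library was 0.25, without the tropomyosin library of replicate 1. Of 10 splits, 1, the real one, gave a median of 0.32 or farther from 0 (highest other, 0.23), and 10 splits are too few for a share under 0.05. A change of mitochondrial RNA with the tropomyosin plasmid and a difference in RNA extraction or selection between groups stay open, and neither was tested.

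The second pattern is transcripts that passed in genes that did not. The median absolute change of the genes of the 6 called transcripts was 0.0868 on the log2 scale, which follows from how the pattern was chosen and does not separate fragments assigned differently among transcripts from a change of splicing. Transcripts under 0.5 FPKM in each library of one side and at least 3 in each library of the other numbered 18 for the real split, with a median of 18 and a highest of 27 over the others, so assignment that varies from library to library may account for such switches. The transcript with the highest value differed in 23.1% of genes between libraries of a group and in 22.8% between groups. A change of splicing with the plasmid stays open for single genes.

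The third pattern is the calls of MIS12, RBMS2 and HES2. For MIS12 and RBMS2 the locus moved with the gene, higher by 1.53 (95% interval 1.05 to 2.01) and 1.31 (0.56 to 2.06). In the tropomyosin libraries these loci stood at 12.2 and 7.94 FPKM, below the genes themselves at 18.2 and 9.67. Locus values are thus not shown to be totals, and they can include the gene's own fragments. They cannot tell whether fragments moved between a gene and unannotated transcripts of its locus, so this stays open. The HES2 locus was higher by 0.40 (0.15 to 0.65) but leaves out the 3' end of the gene. Its value is not the total over HES2, and a shift between transcripts stays open there too. A rise of MIS12 and RBMS2 with the plasmid stays open and was not tested further.

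For the groupings as a whole, 10 splits are too few for a share under 0.05. Genes gave 3 calls against a highest of 13, with 9 of 10 splits at 3 or more, and transcripts gave 6 against 38, with 8 at 6 or more. The split with the most genes and transcripts set control replicates 1 and 3 with tropomyosin replicate 1 against the rest, with 1558 genes at an unadjusted p under 0.05 against 268, which points to a structure of the libraries other than the plasmid. Unannotated genes gave 0 against a highest of 2, and since each of 10 splits reaches 0 by construction, that comparison tests nothing. Gene lists gave 3 against 5, with 5 at 3 or more.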

How the results depend on the processing

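The GC correction, all settings for unannotated transcripts and, for single genes, the filters, plain limma and array weights were chosen after seeing the data. MIS12 and RBMS2 passed under every alternative run for them, with adjusted p up to 0.0396, and HES2 under all in which it was tested but the replicate block (0.0813) and the fit without control replicate 1 (0.0506), with adjusted p otherwise up to 0.0451. With a mean of at least 5, HES2 was not tested, since its mean is lower. Genes called numbered 3 and stayed within 1.5 times under the pseudocount, filters, scalings, array weights, plain limma, the fold limit and the GC correction (2 to 4). Leaving out 1 library gave 2 to 9 genes, with 6 without control replicate 2, 5 without control replicate 3, and 7, 9 and 8 without tropomyosin replicates 1, 2 and 3. Some genes chosen by the naming rule passed only under an alternative. They numbered 1 each with the pseudocount of 0.1, with the GC correction and without control replicate 3, and 2 and 3 without tropomyosin replicates 1 and 2. Transcripts called went from 6 to 2 with a pseudocount of 0.1, to 4 with no filter (CDK16-202 and COPS8-202 at 0.0504) and to 1 with a mean of at least 5, and leaving out 1 library gave 0 (tropomyosin replicate 3) to 28 (tropomyosin replicate 1), with 15, 19 and 20 without control replicates 1, 2 and 3. Unannotated genes stayed at 0 in limma throughout, with 78 to 472 at an unadjusted p under 0.05. Tests for counts were not run, since the values are FPKM. Unannotated transcripts went from 14 to 0 with the pseudocount of 0.1, with no filter and with a mean of at least 5, and to between 0 and 16 without 1 library. Lists past the threshold went from 3 to 0 with an estimated correlation and to 1, the mitochondrial mRNAs, with quantile normalization. Lists outside the first 3 also gained calls. With the GC correction 4 passed, 3 of them shared with the main fit, and without control replicate 1 also 4, with 2 shared. The ribosomal protein list, at a median of -0.00, reached adjusted p under 0.05 without single libraries in either direction, from -0.0820 without control replicate 2 to 0.0917 without control replicate 1, with -0.0751 and 0.0743 without tropomyosin replicates 1 and 3. Of the 36 genes and 559 transcripts in the authors' deposited table, 0 and 5 had a q under 0.05. Apart from fewer features tested or fewer libraries, the cause was not tested. Residual correlations of same-numbered libraries did not show pairing by replicate number, and with 3 libraries per group they cannot exclude it. They were 0.20, -0.02 and 0.02 for genes and 0.07, 0.02 and 0.01 for transcripts. For unannotated genes they were 0.22, 0.15 and -0.10, and for unannotated transcripts 0.04, 0.02 and -0.00. For transcripts 2 of 3 control libraries correlated best with their own number, and 1 of 3 at each other level. With the replicate block, 2 genes and 3 lists passed, and 0 transcripts, 0 unannotated genes and 0 unannotated transcripts in limma, with 702, 241 and 347 at an unadjusted p under 0.05. At this depth and spread, 1.5-fold changes of single genes were mostly missed in simulations (31.3% recovered).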

Other observations

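The comparison of marker lists in this part was chosen after the values were seen. MCF-7 is described in textbooks as a luminal, oestrogen receptor-positive epithelial line. In all 6 libraries VIM, which encodes the mesenchymal filament protein vimentin, was at 205 to 241 FPKM, at or above the 99.1 percentile of listed genes, and CDH2, the N-cadherin gene, stood at 9.57 to 12.3 FPKM. SERPINE1, an inhibitor of plasminogen activation, was at 92.2 ± 8.8 FPKM in the control and 91.3 ± 4.2 in the tropomyosin libraries, and the collagen gene COL5A1 at 63.5 ± 8.4 and 64.9 ± 2.3. EPCAM, an epithelial adhesion molecule, was at 0.918 to 1.53 FPKM and GATA3, a luminal transcription factor, at 0.336 to 0.762 FPKM. The luminal keratin genes KRT8 and KRT18 were high, with KRT18 at 209 ± 21 and 193 ± 6 FPKM. Of the genes fixed as luminal markers, ESR1, CDH1, TFF1, TFF3, KRT19, SPDEF, CLDN3, CLDN4, AGR2 and AGR3 had no value in the table used and were not analysed here. The same holds for MMP1, MMP3, MMP7, MMP9, SPARC, COL3A1 and CDH11 among the markers of epithelial-mesenchymal transition and invasion. Listed were 2 of 18 immune and haematopoietic and 1 of 8 endothelial markers, against 77 of 77 cytosolic ribosomal protein genes. Why genes are missing was not tested, so little or no expression of the missing markers stays open.

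Over the remaining genes of each list, the median percentile within a library was 71.5 to 81.1 for the 25 transition genes and 38.4 to 45.8 for the 10 luminal genes, higher for the former in 6 of 6 libraries. It was 73.8 to 78.8 for 4 of 12 basal and myoepithelial markers and 66.8 to 79.4 for 5 of 14 fibroblast markers. KRT5, KRT14 and TP63 of the former and COL1A2, DCN, LUM, PDGFRA and THY1 of the latter had no listed value. For 3 of 7 genes of the HeLa and HEK293 lineage list, KRT7, CAV1 and CAV2, it was 87.3 to 90.3. KRT7 stood at 451 to 611 FPKM and CAV1 at 27.5 to 33.3. These 3 genes are expressed by many epithelial and other cells. Each of these medians covers only part of its list. The luminal and transition lists hold the genes whose levels drew attention, so their comparison restates those levels. It does not test whether these were cells other than a luminal line in every library. No reference profile of MCF-7 was used, several transition genes are expressed by many cultured lines, and KRT8, KRT18, ELF3 and CLDN7 were above the median gene. The identity of the cells stays open. No gene named in this part passed the test between plasmids, and GATA3 was below the filter and not tested.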
